A study of Homo sapiens with 4 samples.

How the data were processed

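The series holds 4 RNA-seq libraries of A549, an established human lung carcinoma cell line, 2 from wild-type (WT) cells and 2 from cells whose RNase L gene was knocked out (RNase L KO). Per the labels' protocols, the cells were mock transfected with a lipid reagent for 12 h, lysed in hypotonic buffer, and separated into nuclei and cytoplasm. Per the labels' protocols, ribosomal RNA was then depleted from the cytoplasmic RNA and directional paired-end libraries were sequenced.

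The deposited table gives whole-number read counts per gene for each library, separately for exons and for introns. Exon values were handled as estimated counts only because the columns of the deposited table also hold a footer with fractions. The 5 footer lines were left out. All remaining values were whole numbers, so rounding changed none of them, and the column sums equalled the sums in the deposited footer. Intron counts in the deposited table were given for 18475 of 23368 gene rows, and the other 4893 carried a text entry in place of a count. In 28 gene rows the symbol had become a date, and 4 of these shared their name with another. They stayed in the tests and were never named. TopHat2, HTSeq and the genome build hg19 are listed in the submitters' processing notes, without a role. Versions, the gene annotation, the definition of an intron, the strand setting of the counting and the handling of duplicate reads are not given in the sources used here. Reads from overlapping or antisense genes can therefore not be told apart with certainty, and counts of near-identical gene copies are uncertain.

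Groups and replicate numbers came from the sample titles. The labels do not say how many clones the RNase L KO cells came from, or whether the WT cells are their parent. Genotype can therefore not be separated from other differences between the cell lines. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Exon and intron counts together ranged from 43592492 to 50317980 per library. A floor of 3 counts corresponded to between 0.0740 and 0.0787 exon CPM. Intervals and floors cover counting error only, because reads copied from the same fragment during amplification are not independent.

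Exon counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr by genotype with its minimum count of 10) in R 4.3.3, with genotype as the only term. Intron counts were tested in the same way, with the effective library sizes of the exon counts of the same library, so that a change shared by all introns stayed visible. Exon levels are given as CPM, and intron levels as intron CPM, which divides intron counts by the exon library size. For each gene passing both filters, the change of intron counts relative to exon counts was tested as an interaction in a single edgeR model with library as a term. Benjamini-Hochberg adjustment was used throughout, with a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of its F statistic. The intron share of each library was compared by an exact two-sided permutation test.

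There were 28 gene lists and a rule for the genes named, all fixed before the data were examined. The lists cover the OAS and RNase L pathway, interferon-stimulated genes, interferons, dsRNA sensing, NF-kB and inflammation, immediate early genes, the integrated stress and unfolded protein response, ribosomal proteins, mitochondrial mRNAs, oxidative phosphorylation, histones, nuclear-retained RNAs, snoRNA hosts, mRNAs translated at the endoplasmic reticulum, lung epithelial and carcinoma markers, NRF2 targets, mesenchymal genes, S phase, G2 and M phase, p53 targets, cholesterol and fatty acid synthesis, hypoxia and glycolysis, splicing regulators, RNA decay, class I antigen presentation, and fibroblast, leukocyte and endothelial markers. Lists with at least 3 tested members were tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01. As an alternative the correlation was estimated, which leaves camera only the few residual degrees of freedom of 4 libraries. That alone raises p, so a call lost with an estimated correlation cannot be laid to correlated genes. The named genes were RNASEL and, per direction, the 10 with the largest change among those past the threshold, without overlap between the genotypes and with a mean of at least 5 exon CPM, or of at least 1 intron CPM. Per list, up to 4 members past the threshold were named by abundance, filled to 2 by p. Small RNA genes were skipped.

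The steps were tested on simulated counts with the means and library sizes of these data. In exon counts, 41.8% of genes changed 2-fold and 83.3% of those changed 4-fold were recovered over 12731 genes, with 5 false among 126 calls. In intron counts these shares were 20.6% and 69.8% over 10632 genes, with 5 false among 92 calls. For the interaction they were 1.2% and 33.3% over 10018 genes, with 7 false among 63 calls. Camera called the simulated list shifted 1.5-fold in exon counts and 0 of the other lists. Simulated genes varied independently, so this step could not show false list calls that arise from correlated genes. Both genotypes were simulated with the same spread, and no shift shared by all introns was simulated. Each gene was given the dispersion of the trend. Exon and intron counts were drawn independently, without the deviations that exons and introns of a real library can share.

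Alternatives were relative log expression size factors, no low-count filter, DESeq2 1.42.0, the replicate number as a block, a minimum fold of 1.5, scaling by the intron counts themselves, an estimated inter-gene correlation, the rotation test fry, and leaving out each library in turn. With a library left out, the single library of that genotype was assumed to vary like the other genotype. Calls without a WT library therefore rest on the spread of the RNase L KO pair, and those without a RNase L KO library on that of the WT pair. Intron lengths came from GENCODE release 29 and gene neighbours from RefSeq on GRCh38.p14. Both describe another build than hg19, so they were joined by gene name only and no coordinates are given. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.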

Results

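Cytoplasmic RNA of A549 cells was sequenced from 2 WT and 2 RNase L KO libraries, each 12 h after mock transfection. RNase L is an endoribonuclease activated by 2-5A, the product of the OAS enzymes, which sense double-stranded RNA. The title of the series concerns double-stranded RNA encoded in introns, and the deposited counts separate exons from introns, so that the genotypes could be compared in both. WT replicates 1 and 2 held 38419509 and 38083276 exon counts and 6040712 and 5509216 intron counts. RNase L KO replicates 1 and 2 held 40213037 and 40057887 exon counts and 8043534 and 10260093 intron counts.

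RNASEL, the targeted gene, had 712 and 540 exon counts in the WT libraries and 108 and 69 in the RNase L KO libraries. Its level was 16.4 ± 3.14 CPM, the edgeR unit of counts scaled by effective library size, in WT and 2.20 ± 0.658 in RNase L KO (SD, n = 2 each). The log2 fold change was -2.90 (SE 0.346, adjusted p = 0.0192, edgeR with Benjamini-Hochberg adjustment). RNASEL introns held 5 and 13 counts in WT, and 32 and 0 in RNase L KO. The call was lost without WT replicate 1 (adjusted p = 0.117, edgeR, Benjamini-Hochberg) and without WT replicate 2 (adjusted p = 0.0603), with log2 fold changes of -2.68 and -3.08.

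Exon counts of 32 genes rose and those of 57 fell in RNase L KO, among 13033 genes tested. NR5A2, a nuclear receptor, rose from 3.30 ± 1.79 to 68.4 ± 17.7 CPM (SD, n = 2 each), a log2 fold change of 4.37 (SE 0.411, adjusted p = 0.00685, edgeR, Benjamini-Hochberg). KIAA1244 rose by 3.46 on the log2 scale, DSE, an epimerase of dermatan sulfate synthesis, by 3.12, and SPATA18 by 2.90. The forkhead transcription factor FOXC1 rose by 2.27, the tight junction protein gene CLDN2 by 1.98, SH3BGRL2 by 1.83, the metalloproteinase gene MMP24 by 1.81 and the tryptophan dioxygenase gene TDO2 by 1.64. UGT1A9 rose by 2.94, but shares exons with the other genes of its locus and is uncertain.

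Without WT replicate 1 the calls of DSE, UGT1A9, SPATA18, FOXC1, CLDN2, SH3BGRL2, MMP24 and TDO2 were lost, and without WT replicate 2 the same calls except that of FOXC1.

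Among the genes that fell, FGF13, a member of the fibroblast growth factor family, had 796 exon reads in the WT libraries and 1 in the RNase L KO libraries, a ratio of 838 with a 95% counting interval of 150 to 33140. Such intervals are too narrow where replicates spread beyond counting error, and at 5 to 20 reads the variance between replicates was 11.6 times the mean. GALNT13, which starts O-glycosylation, fell by 6.88 on the log2 scale, and the ephrin receptor EPHA3 fell by 5.24. KRT81, a hair keratin with near-identical relatives, fell from 206 ± 29.9 to 8.75 ± 2.33 CPM (SD, n = 2 each), a log2 fold change of -4.56 (SE 0.248, adjusted p = 0.00199, edgeR, Benjamini-Hochberg). CADPS2 fell by 5.15, the signalling protein gene BMP2 by 4.25, TBC1D4 by 4.19, NCKAP5 by 3.98 and EDIL3 by 3.95, the last not called without WT replicate 1 or without WT replicate 2. HIST1H2BH fell by 7.63, but belongs to a family of near-identical histone genes and is uncertain. Counts of calls depended on the libraries kept: 5 higher and 16 lower without WT replicate 1, 5 and 15 without WT replicate 2, 914 and 1132 without RNase L KO replicate 1, and 336 and 508 without RNase L KO replicate 2. DESeq2 called 237 higher and 293 lower, and with no low-count filter edgeR called 83 and 123.

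**Figure D1:**
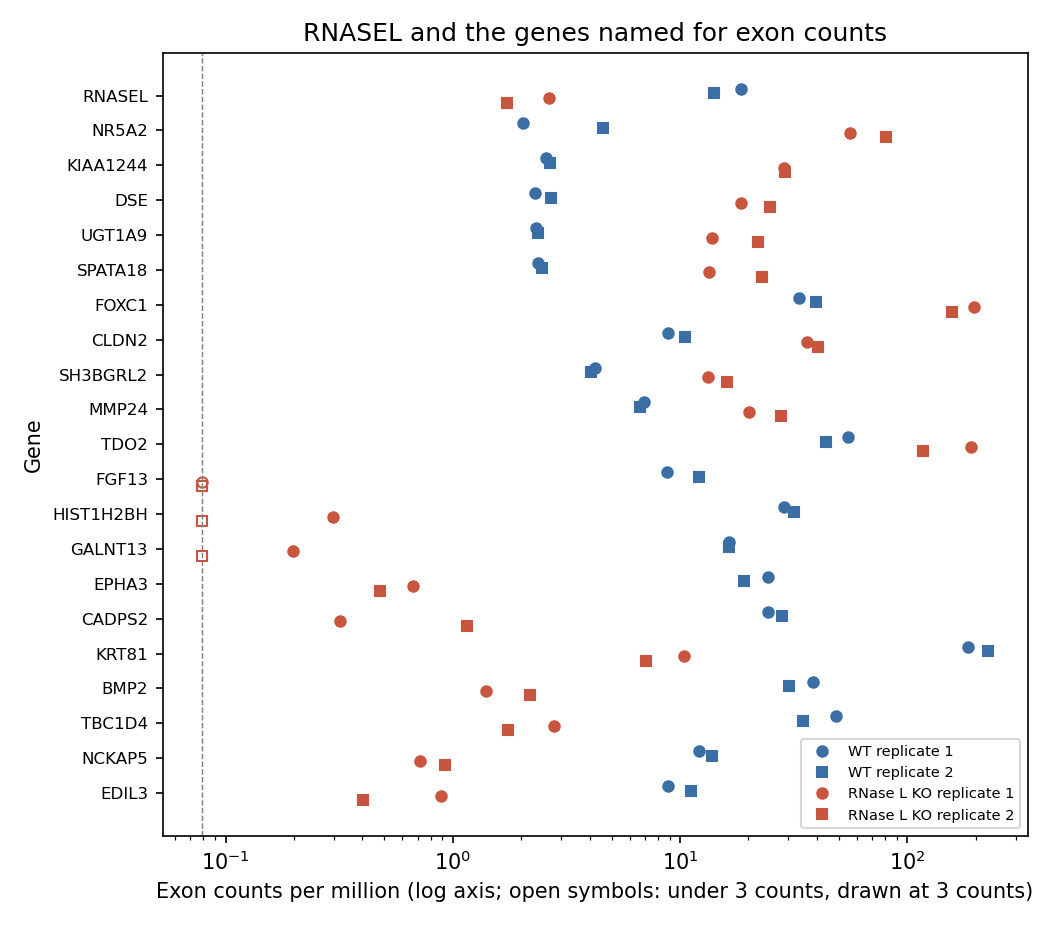
Exon CPM (log axis) of RNASEL and the 20 other genes named for exon counts, with blue symbols for WT, red for RNase L KO, circles for replicate 1 and squares for replicate 2. Open symbols mark libraries under 3 counts, drawn at the level of 3 counts. The genotypes did not overlap in any gene drawn, as the naming rule required.

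The intron share was 13.6% and 12.6% in WT replicates 1 and 2, and 16.7% and 20.4% in RNase L KO replicates 1 and 2. It averaged 13.1 ± 0.671% in WT and 18.5 ± 2.63% in RNase L KO (SD, n = 2 each), a difference of 5.42 percentage points, or of 3.56 without RNase L KO replicate 2. MALAT1, a long RNA retained in the nucleus, moved with it: exon counts were 4671 and 4098 CPM in WT and 8711 and 9098 CPM in RNase L KO, a log2 fold change of 1.02 (SE 0.124, adjusted p = 0.0205, edgeR, Benjamini-Hochberg). NEAT1, another nuclear RNA, stood at 158 ± 24.2 CPM in WT and 245 ± 49.5 in RNase L KO, with a log2 fold change of 0.63 that did not pass (adjusted p = 0.209, edgeR, Benjamini-Hochberg). The MALAT1 call was lost without WT replicate 1 (adjusted p = 0.277, edgeR, Benjamini-Hochberg) and without WT replicate 2 (adjusted p = 0.410). For the intron share, the exact two-sided permutation test gave p = 0.33, the smallest p that 2 against 2 libraries allow. Counting error was far smaller than the spread between libraries, the 95% Wilson interval of WT replicate 1 being 13.58% to 13.60%.

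**Figure D2:**
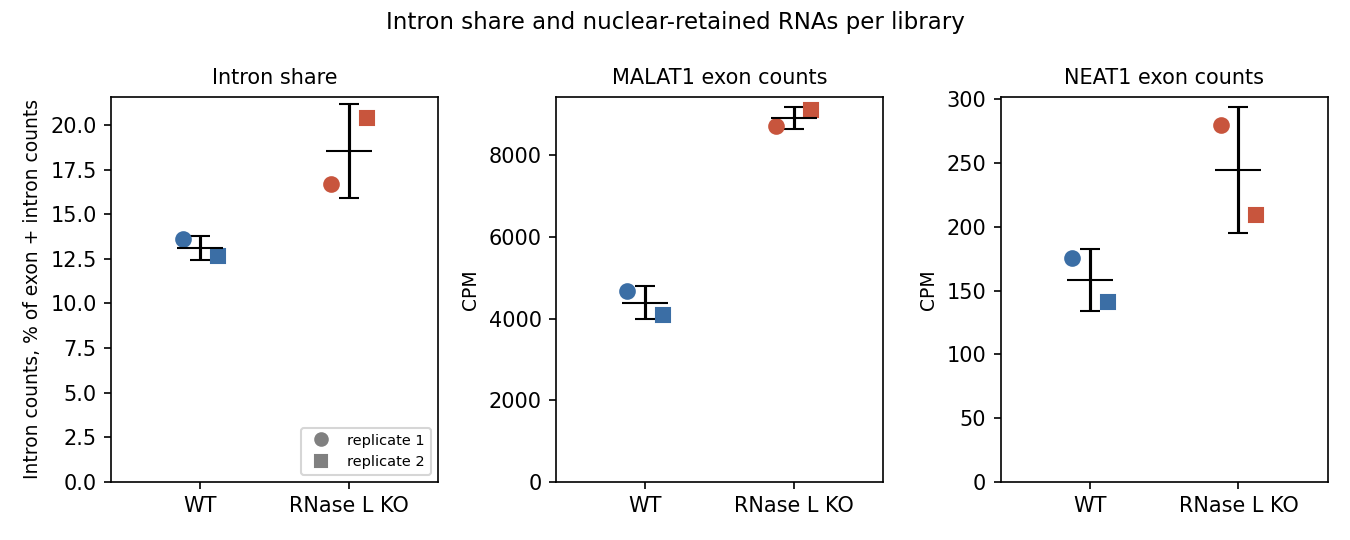
Intron share of all exon and intron counts (%), and exon CPM of MALAT1 and NEAT1, in the 4 libraries, with bars at the mean ± SD of each genotype (n = 2). The RNase L KO libraries, at 16.7% and 20.4% intron share, lie above the WT libraries, at 13.6% and 12.6%.

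Intron counts of 1417 genes rose and those of 80 fell in RNase L KO, among 10994 genes tested. The intron fit of edgeR gave every gene the spread of a shared trend (infinite prior degrees of freedom). The exon fit kept part of each gene's own spread (5.46 prior degrees of freedom). Numbers of calls and p-values are therefore not comparable between introns and exons. The median intron log2 fold change over all genes was 0.54, and 82.5% of genes lay above 0. Scaling the libraries by their own intron counts lowered the log2 fold changes by a median of 0.53 and gave 292 genes higher and 276 lower (edgeR, Benjamini-Hochberg). Changes of single genes are given under exon scaling and then relative to this shift, under intron scaling. NR5A2 introns rose by 4.83 and by 4.28, SPATA18 introns by 4.31 and by 3.80, and introns of the glycosyltransferase gene MGAT4A by 4.15 and by 3.54. SVEP1 introns rose from 2.93 ± 1.21 to 41.6 ± 15.4 intron CPM (SD, n = 2 each), or by 3.83 and by 3.28, and IGFBP7 introns by 3.66 and by 3.11. PLEKHG1 rose by 5.04 and by 4.54, and TMCC2 by 3.92 and by 3.48. SALL1, a zinc finger transcription factor gene, had 0 intron reads in WT and 196 in RNase L KO, at least 62.1-fold higher against a floor of 3 counts over the group, and lies on chromosome 16. The semaphorin receptor gene PLXNC1 and MED29, at 2.15 ± 0.221 and 1.91 ± 1.38 intron CPM in RNase L KO (SD, n = 2 each), passed under exon scaling and not under intron scaling (adjusted p = 0.0797 and 0.224, edgeR, Benjamini-Hochberg), and their calls were lost without WT replicate 2 and without RNase L KO replicate 2.

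Among the introns that fell, those of MYOM3, a sarcomere protein gene, had 198 reads in WT and 0 in RNase L KO, at least 69.5-fold lower against the same floor. FGF13 introns had 212 and 3 reads, a ratio of 74.4 with a 95% counting interval of 25.1 to 364, and were not called without WT replicate 1. GALNT13 introns fell from 38.6 ± 3.17 to 0.574 ± 0.218 intron CPM (SD, n = 2 each), a log2 fold change of -6.07 under exon scaling and -6.61 under intron scaling. ZNF804A introns stood at -5.94 and -6.46, those of the thyroid hormone receptor gene THRB at -5.38 and -5.97, CYP4F11, uncertain for its near-identical relatives, at -5.25 and -5.84, the potassium channel gene KCNT2 at -5.05 and -5.49, and the collagen gene COL3A1 at -5.00 and -5.46. FMN2 introns stood at -4.69 and -5.22, and those of the netrin receptor gene UNC5D at -4.69 and -5.15. The calls of higher and lower introns numbered 133 and 34 without WT replicate 1, 69 and 39 without WT replicate 2, 3705 and 95 without RNase L KO replicate 1, and 593 and 69 without RNase L KO replicate 2. DESeq2 called 2261 and 42.

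**Figure D3:**
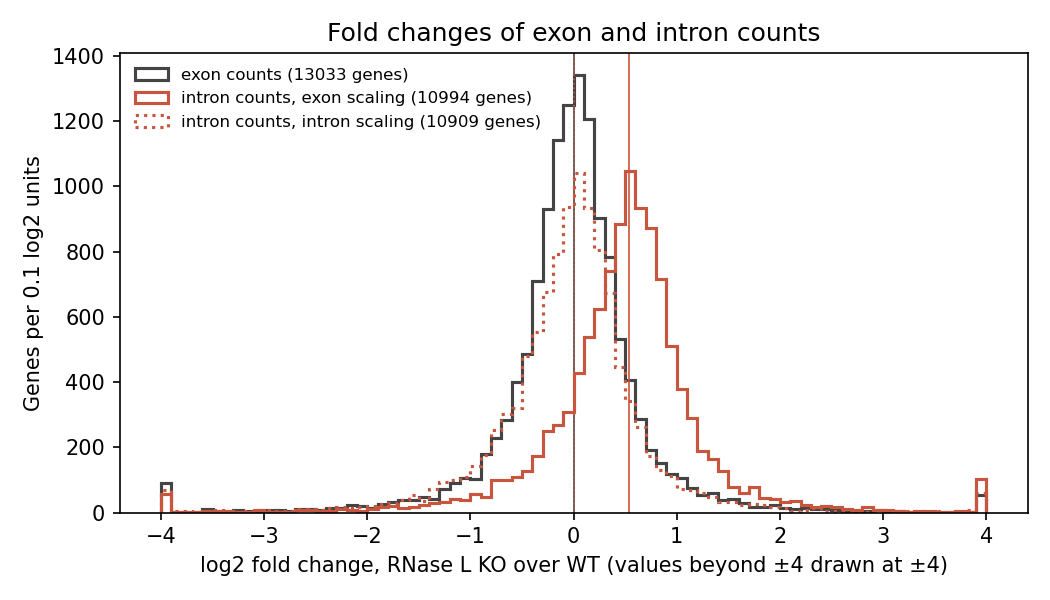
Distribution over genes of the log2 fold change, RNase L KO over WT, of exon counts (grey) and of intron counts under exon scaling (red) and intron scaling (dotted), with vertical lines at the medians and values beyond 4 drawn at the edges. The intron median lies at 0.54 under exon scaling and near 0 under intron scaling, like that of the exon counts.

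Of 10329 genes tested in both, 27 were higher in exon counts and 1398 in intron counts, and 21 were in both sets, against 3.65 for independent sets. In the lower direction the sets held 50 and 72 genes and shared 23, against 0.349 for independent sets. Exon and intron counts come from the same libraries, so part of this overlap can be shared chance. Genes called higher in introns had a median log2 fold change of 1.04 in introns and 0.21 in exons. They were chosen by their intron change, which raises the intron median. Over all genes tested, the medians were 0.54 in introns and 0.0022 in exons. Across the 10329 genes, which are not independent replicates, Pearson's r of the exon and intron fold changes was 0.41 and Spearman's rho 0.33. With the exon change from one replicate number and the intron change from the other, r was 0.27 and 0.22. Each of these changes rests on a single library per genotype, whose added noise lowers r by itself. The drop from 0.41 therefore does not measure shared chance alone. Over 9334 genes with at least 100 counts of each kind, with all libraries, r was 0.50. The interaction model of edgeR asks whether introns moved apart from the exons of the same gene. After Benjamini-Hochberg adjustment, 0 of 10329 genes passed (edgeR, smallest adjusted p = 0.115), and 1812 higher and 64 lower had an unadjusted p under 0.05. The median change of introns relative to exons was 0.54 on the log2 scale, with 83.4% of genes above 0. In simulated counts, with exons and introns drawn independently, this test recovered 1.2% of 2-fold and 33.3% of 4-fold changes. Its power in real libraries, where exons and introns can share deviations, was not measured. The lack of calls therefore does not show that introns and exons moved alike. After adjustment, the interaction called 1 gene higher with no low-count filter, and 44 higher and 7 lower with the replicate number as a block.

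Targets of p53 were higher in RNase L KO as a list (camera, Benjamini-Hochberg adjusted p = 7.5e-12, but adjusted p = 0.405 with an estimated correlation). Of 22 tested members, 2 rose over all genes tested and 11 when adjusted over the list alone, none fell, and 21 had a positive fold change, with a median log2 fold change of 0.64. TP53INP1, a p53-induced nuclear protein gene, rose from 52.6 ± 2.13 to 145 ± 17.5 CPM (SD, n = 2 each), and SPATA18, a mitochondrial quality control gene, from 2.42 ± 0.0626 to 18.1 ± 6.70 CPM. MDM2, the ubiquitin ligase of p53, had a log2 fold change of 0.71 that did not pass over all genes (adjusted p = 0.0637, edgeR, Benjamini-Hochberg). The rotation test fry of limma gave the list adjusted p = 0.0595 (Benjamini-Hochberg). The calls of TP53INP1 and SPATA18 were lost without WT replicate 1 and without WT replicate 2, and that of the list was kept without each library. MALAT1 exon counts and the intron share were higher in the same RNase L KO libraries.

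Immediate early genes, which respond within minutes to stimulation, were also higher as a list (camera, Benjamini-Hochberg adjusted p = 0.00153, but adjusted p = 0.405 with an estimated correlation). Of 23 tested members, 0 passed over all genes and 7 were higher when adjusted over the list alone, among them KLF6 and ZFP36, at log2 fold changes of 0.78 and 0.66. Without RNase L KO replicate 1 this list was not called (adjusted p = 0.0654, camera, Benjamini-Hochberg). The mRNAs translated at the endoplasmic reticulum were higher, with 32 of 43 members above 0 and a median log2 fold change of 0.25 (camera, Benjamini-Hochberg adjusted p = 0.00153, but adjusted p = 0.405 with an estimated correlation). None of them passed over all genes or when adjusted over the list alone, with CD151 at 1.10 and EGFR at 0.97. Nuclear-retained RNAs were higher (camera, Benjamini-Hochberg adjusted p = 0.00405, but adjusted p = 0.405 with an estimated correlation). Of 10 members tested 9 were above 0, and MALAT1 was the 1 that rose, both over all genes and when adjusted over the list alone.

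Markers of lung epithelium and carcinoma were called higher (camera, Benjamini-Hochberg adjusted p = 0.0365, but adjusted p = 0.416 with an estimated correlation), although their mean log2 fold change was -0.06 and their median 0.06. Of 13 tested members, 2 rose over all genes, LPCAT1, a surfactant lipid enzyme gene, by 1.40 and CLDN2 by 1.98 (neither called without WT replicate 1 or without WT replicate 2), and 5 were higher and 1 lower when adjusted over the list alone. The call was absent without each of the libraries in turn, with adjusted p of 0.271 without WT replicate 1, 0.338 without WT replicate 2, 0.138 without RNase L KO replicate 1 and 0.0794 without RNase L KO replicate 2 (camera, Benjamini-Hochberg).

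Interferon-stimulated genes were lower as a list (camera, Benjamini-Hochberg adjusted p = 0.0229, but adjusted p = 0.405 with an estimated correlation). Of 36 tested members, 1 fell over all genes, and 1 was higher and 3 were lower when adjusted over the list alone. IFITM2, which restricts virus entry, fell from 45.7 ± 3.87 to 10.9 ± 3.29 CPM (SD, n = 2 each), and the ubiquitin-like modifier ISG15 stood at a log2 fold change of -1.09. The IFITM2 call was lost without WT replicate 1 and without WT replicate 2, and its counts are uncertain for its closely similar relative IFITM3. This list was not called without WT replicate 1 (adjusted p = 0.177, camera, Benjamini-Hochberg), without WT replicate 2 (adjusted p = 0.0805) or without RNase L KO replicate 1 (adjusted p = 0.220). Cytosolic ribosomal proteins were lower, with 52 of 76 members below 0 and a median log2 fold change of -0.16 (camera, Benjamini-Hochberg adjusted p = 0.0197, but adjusted p = 0.804 with an estimated correlation). None passed over all genes and 2 were lower when adjusted over the list alone, RPS3 at -1.87 and RPS2 at -0.77. RPS2 lies on chromosome 16, whose 571 tested genes had a median log2 fold change of -0.33, and many ribosomal protein genes have near-identical pseudogenes. Without RNase L KO replicate 2 the ribosomal list was higher (adjusted p = 0.00921, camera, Benjamini-Hochberg), and without WT replicate 2 it was not called (adjusted p = 0.265).

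Fibroblast markers were lower (camera, Benjamini-Hochberg adjusted p = 4.3e-06, but adjusted p = 0.405 with an estimated correlation), with only 3 members tested. COL3A1 fell from 6.05 ± 0.353 to 0.362 ± 0.198 CPM (SD, n = 2 each), the 1 member past the threshold over all genes, and all 3 were lower when adjusted over the list alone. Without WT replicate 1 or without WT replicate 2 the COL3A1 call was lost. LUM, a collagen-binding proteoglycan gene, had 161 reads in WT and 2 in RNase L KO, a ratio of 84.7 with a 95% counting interval of 23.1 to 706, and COL1A1 was at a log2 fold change of -0.59.

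**Figure D4:**
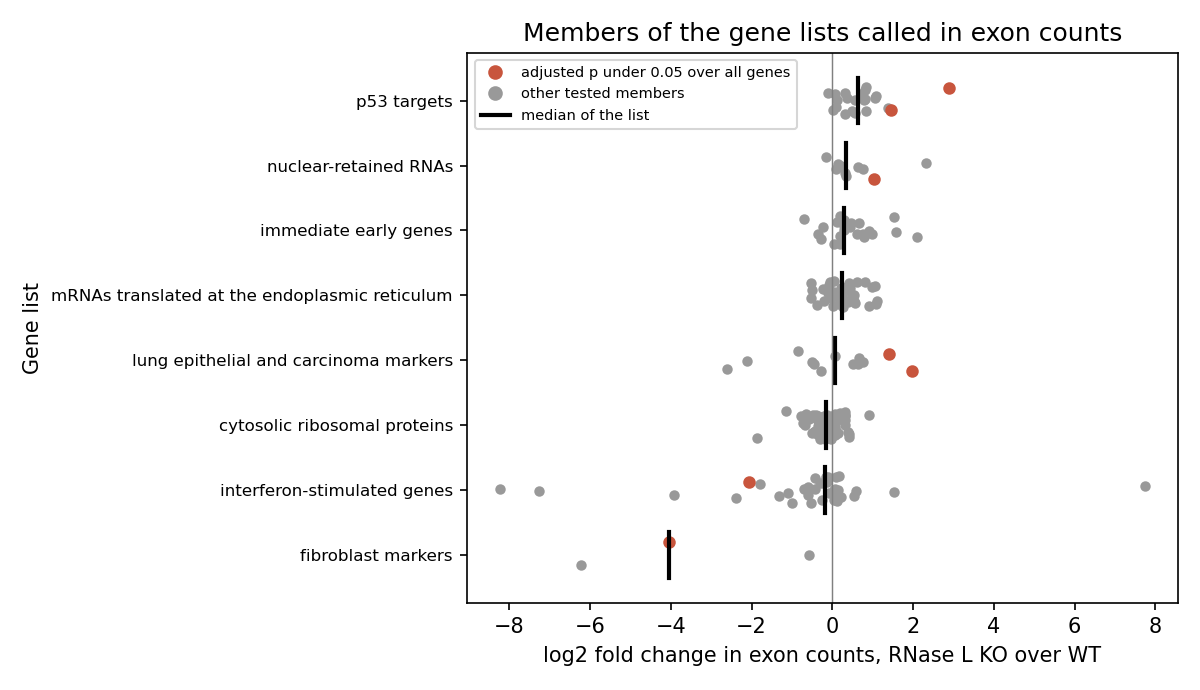
Log2 fold change in exon counts, RNase L KO over WT, of the tested members of the 8 gene lists called by camera at the preset correlation, with red points for members past the threshold over all genes and black lines at list medians, vertical scatter being only for display. Members with 0 counts in a genotype are drawn at their fitted value, which is not a bound. The p53 targets have the highest median, 0.64, and the fibroblast markers the lowest, -4.05.

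Camera called none of the other lists in exon counts, whose adjusted p from camera with Benjamini-Hochberg adjustment follow. The OAS and RNase L pathway had adjusted p = 0.0654, with RNASEL the 1 of 7 members that fell over all genes and OAS3, at -0.64, the other of 2 lower when adjusted over the list alone. Genes of dsRNA sensing had adjusted p = 0.988 and 0 members past the threshold either way, with ADAR, the RNA editing enzyme gene, at -0.62 and ZC3HAV1 at 0.55. The test pointed down and the median, 0.06, was positive. NF-kB and inflammatory genes had adjusted p = 0.554 and 0 of 16 members passing either way, with NFKBIZ at 1.93. The integrated stress and unfolded protein response had adjusted p = 0.554, with 0 of 30 members passing over all genes and 1 lower when adjusted over the list alone, the asparagine synthetase gene ASNS, at 237 ± 5.74 CPM in WT and 118 ± 24.2 CPM in RNase L KO (SD, n = 2 each). Oxidative phosphorylation had adjusted p = 0.106, with 0 of 34 passing over all genes and 1 lower when adjusted over the list alone, SDHB at -0.81. Replication-dependent histones had adjusted p = 0.554 and 0 of 20 passing either way, with a median of -0.18 and a mean of 0.14. The snoRNA host genes had adjusted p = 0.132, with 0 of 16 passing over all genes and 1 lower when adjusted over the list alone, SNHG3 at -0.65. Camera called oxidative phosphorylation and the snoRNA hosts lower without RNase L KO replicate 1 (adjusted p = 6.2e-05 and 0.00264, Benjamini-Hochberg), and the histones lower without RNase L KO replicate 2 (adjusted p = 0.0359).

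Targets of NRF2 had adjusted p = 0.554 in camera with Benjamini-Hochberg adjustment. AKR1C3, an aldo-keto reductase gene with near-identical copies, was the 1 of 27 that rose over all genes, by 0.90, and 2 were higher and 2 lower when adjusted over the list alone. Mesenchymal genes had adjusted p = 0.519, with 1 of 19 lower over all genes, the repressor ZEB2, which fell from 21.9 ± 0.119 to 5.77 ± 0.495 CPM (SD, n = 2 each), and 1 higher and 3 lower when adjusted over the list alone. S phase genes had adjusted p = 0.554 and 0 of 23 passing either way, with FEN1 at -0.46. Genes of G2 and M phase had adjusted p = 0.562, with 1 of 26 lower over all genes, the checkpoint kinase BUB1B, which fell by 1.15, and 1 higher and 1 lower when adjusted over the list alone. The test pointed down, as did the mean, -0.07, and the median was 0.01. Cholesterol and fatty acid synthesis had adjusted p = 0.554 and 0 of 28 passing either way, with FDPS at -0.80. Hypoxia and glycolysis had adjusted p = 0.178, with 0 of 27 passing over all genes and 3 higher when adjusted over the list alone, including ADM at 1.37, and fry of limma, which does not compare a list with other genes, called it higher (adjusted p = 0.0157, Benjamini-Hochberg). Splicing regulators had adjusted p = 0.966 and 0 of 39 passing either way, with CLK1 at 0.50. RNA decay genes had adjusted p = 0.966 and 0 of 34 passing either way, with EXOSC8 at -0.82. Class I antigen presentation had adjusted p = 0.966 with 0 of 7 passing either way, and leukocyte markers adjusted p = 0.958 with 0 of 3. The 2 endothelial markers measured were too few for the test and neither passed. None of the 9 interferon genes in the table passed the filter, and the deposited table lists none of the mitochondrial mRNAs. The calls of AKR1C3, ZEB2 and BUB1B were lost without WT replicate 1 and without WT replicate 2.

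In intron counts, p53 targets were again higher relative to all other genes (camera, Benjamini-Hochberg adjusted p = 6.4e-05, but adjusted p = 0.792 with an estimated correlation). Of 21 tested members, 12 rose over all genes and 13 when adjusted over the list alone, 5 rose under intron scaling, and all 21 lay above 0. MDM2 introns rose from 57.1 ± 9.72 to 131 ± 20.2 intron CPM (SD, n = 2 each), and TNFRSF10B, a death receptor gene, from 34.0 ± 7.09 to 71.1 ± 12.2. Genes of G2 and M phase were higher (camera, Benjamini-Hochberg adjusted p = 0.0313, but adjusted p = 0.792 with an estimated correlation), with 9 of 26 rising over all genes, 13 when adjusted over the list alone and 3 under intron scaling. CENPF introns, of a kinetochore protein gene, rose by 1.13 on the log2 scale and by 0.60 under intron scaling. That list was not called under intron scaling (adjusted p = 0.0668, camera, Benjamini-Hochberg), with the replicate number as a block (adjusted p = 0.0541) or without WT replicate 2 (adjusted p = 0.160). The rotation test fry of limma, which compares a list with no change and not with other genes, called neither list (adjusted p = 0.185 for each, Benjamini-Hochberg). The calls of MDM2, TNFRSF10B and CENPF introns were lost without WT replicate 1 and without WT replicate 2. MALAT1 exon counts and the intron share were higher in the same libraries.

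Camera called no other list in intron counts under exon scaling with all libraries, and counts of members follow as those over all genes and then those adjusted over the list alone, beside adjusted p from camera with Benjamini-Hochberg adjustment. Hypoxia and glycolysis had 7 of 22 higher, then 11 (adjusted p = 0.0878), with 3 under intron scaling, among them the glycolytic regulator PFKFB3. The mRNAs translated at the endoplasmic reticulum had 9 of 42 higher, then 13 (adjusted p = 0.204), with 3 under intron scaling, including ITGB1, whose introns rose by 1.25. Splicing regulators had 6 of 35 higher, then 8 (adjusted p = 0.0900), all 35 being above 0 under exon scaling with a median of 0.61, and at 0.07 under intron scaling. HNRNPH1, a splicing factor gene, was the 1 that passed under both scalings. NRF2 targets had 6 of 26 higher and 1 lower, then 10 and 1 (adjusted p = 0.119), and 3 and 1 under intron scaling, with AKR1C2 introns up by 2.22 and uncertain for its near-identical copies. Mesenchymal genes had 3 of 16 higher and 1 lower, then 4 and 1 (adjusted p = 0.566), and 2 and 1 under intron scaling, with TGFB2 up by 2.38. Lung markers had 3 of 9 higher and 1 lower, then 6 and 1 (adjusted p = 0.566), and 1 and 1 under intron scaling, the transporter gene ABCA3 being the 1 that was lower, at -1.25. ABCA3 lies on chromosome 16, whose 450 genes tested in introns had a median log2 fold change of 0.09. Nuclear-retained RNAs had 2 of 3 higher, then 3 (adjusted p = 0.0900), and 1 under intron scaling, with PVT1 up by 0.95 and by 0.41 under intron scaling.

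RNA decay genes had 3 of 32 higher, then 0 (adjusted p = 0.750, camera, Benjamini-Hochberg), with XRN2 at 0.79, but 0 higher and 2 lower under intron scaling. Interferon-stimulated genes had 1 of 22 higher, then 1 (adjusted p = 0.196), PARP14 at 1.13, and dsRNA sensing genes 1 of 20, then 0 (adjusted p = 0.442), the kinase TBK1 at 0.80. Under intron scaling neither PARP14 nor TBK1 passed, and the calls were 1 lower interferon-stimulated gene, PLSCR1 at -0.88, and 2 lower dsRNA sensing genes, ADAR at -0.89 and ADARB1 at -1.12, PLSCR1 and ADARB1 being chosen after their values were seen. NF-kB genes had 1 of 11, then 1 (adjusted p = 0.574), NFKBIZ at 1.17, and immediate early genes 1 of 15, then 1 (adjusted p = 0.618), KLF6 at 1.04. Ribosomal proteins had 1 of 70 higher, then 0 (adjusted p = 0.457), RPL23 at 0.99, and S phase genes 1 of 23, then 1 (adjusted p = 0.610), SLBP at 1.07. Under intron scaling 0 members of these last 4 lists passed. Cholesterol synthesis had 1 of 27 lower, then 1 (adjusted p = 0.0797), PCSK9 at -1.51, which fell under both scalings, and 2 lower under intron scaling. The OAS and RNase L pathway (5 tested, adjusted p = 0.457), the stress response (25, adjusted p = 0.0900), oxidative phosphorylation (33, adjusted p = 0.0900), snoRNA hosts (10, adjusted p = 0.0900) and class I antigen presentation (4, adjusted p = 0.457) had 0 members passing either way under exon scaling (camera, Benjamini-Hochberg). Under intron scaling 3 members of the stress response, 1 of oxidative phosphorylation and 1 of the snoRNA hosts were lower, among them ASNS at -1.12. Interferons, histones and the fibroblast, endothelial and leukocyte markers had under 3 members tested, of which COL3A1 was the 1 past the threshold. Medians were positive under exon scaling for all lists tested in introns, and under intron scaling those of the NF-kB genes, stress response, ribosomal proteins, oxidative phosphorylation, snoRNA hosts, mesenchymal genes, S phase, cholesterol synthesis, RNA decay and antigen presentation turned negative. Under intron scaling camera called cholesterol synthesis and the stress response lower than other genes (adjusted p = 0.000504 and 0.0127, Benjamini-Hochberg). Without RNase L KO replicate 2 it called cholesterol synthesis (adjusted p = 0.00371), oxidative phosphorylation (0.0348) and fibroblast markers (0.0348) lower and splicing regulators (0.00377) higher, Benjamini-Hochberg adjusted. It called fibroblast markers lower without RNase L KO replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.00599) and without WT replicate 2 (7.4e-05), and endothelial markers lower without WT replicate 1 (0.0168). Camera compares a list with the other genes, so its direction was down for several lists with positive medians, and for the immediate early genes despite a median of 0.75. Of the intron calls named for these lists under exon scaling, only those of TGFB2 and COL3A1 were kept without each library in turn, and that of AKR1C2 was lost without WT replicate 1 only.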

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

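Counts of changed genes kept within 1.5 times under relative log expression factors (32 higher and 57 lower in exons, 1490 and 81 in introns) and, in introns, with no low-count filter (1224 and 69). Most other settings moved them more, and no call of a single gene named reversed under the alternatives run. For exon counts (32 higher, 57 lower), edgeR called 83 and 123 with no low-count filter and 8 and 26 against a minimum fold of 1.5, and DESeq2 called 237 and 293. For intron counts (1417 higher, 80 lower), a minimum fold of 1.5 left 150 and 42, DESeq2 called 2261 and 42, and intron scaling gave 292 and 276, of which 363 calls were shared with the 1497 under exon scaling. The interaction called 1 gene higher with no low-count filter. Leaving out each library in turn gave 5 to 914 higher and 15 to 1132 lower genes in exons, 69 to 3705 higher and 34 to 95 lower in introns, and 0 to 138 higher and 0 to 19 lower in the interaction. Without a WT library the spread came from the RNase L KO pair alone, and without a RNase L KO library from the WT pair. At 100 to 1000 reads, the variance between replicates was 16.4 times the mean in WT and 38.1 times in RNase L KO exon counts. In intron counts it was 15.4 and 33.7 times. Exon and intron calls lost without a WT library may therefore reflect the wider spread of the RNase L KO pair rather than a smaller change. Interaction calls moved the other way, and no further cause was tested. RNASEL ranged from -3.24 to -2.62 on the log2 scale, and was not called without WT replicate 1 (-2.68) or WT replicate 2 (-3.08). Pearson's r of the exon and intron changes was 0.50, 0.27 and 0.22 in place of 0.41.

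With the replicate number as a block (replicate block), exon calls numbered 20 higher and 40 lower, intron calls 223 and 48, and interaction calls 44 and 7, and the intron lists called higher numbered 1. Deviations of same-numbered libraries correlated at -0.078 in exon and 0.037 in intron counts, so the numbers were not taken to pair the libraries.

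Of the exon lists, 5 were called higher and 3 lower. Camera with an estimated inter-gene correlation has few degrees of freedom here, so a lost call does not show that correlated genes made it. Estimates lay under the preset 0.01 for mRNAs translated at the endoplasmic reticulum (-0.0027), interferon-stimulated genes, lung markers and nuclear-retained RNAs. They lay above it for the other lists called. For the endoplasmic reticulum list the unadjusted camera p still rose from 0.00024 to 0.0486. With an estimated inter-gene correlation 0 and 0 were called, by fry 4 and 1 (the 4 being nuclear-retained RNAs, mRNAs translated at the endoplasmic reticulum, lung markers, and hypoxia and glycolysis, which camera did not call, without p53 targets and immediate early genes), and without each library 3 to 5 and 1 to 4. Cytosolic ribosomal proteins turned from lower to higher without RNase L KO replicate 2 (adjusted p = 0.00921, camera, Benjamini-Hochberg; 3.5e-12 to 0.265 without each other library), and the cause was not tested. Of the intron lists, 2 were called higher and 0 lower. An estimated correlation and fry each called 0 higher, intron scaling 1 higher and 2 lower (cholesterol synthesis and the stress response), and leaving out each library 1 to 3 higher and 1 to 3 lower. The intron share difference lay between 3.56 (without RNase L KO replicate 2) and 7.28 (without RNase L KO replicate 1) percentage points. Over the alternatives of the single genes named, 489 exon values kept their side of the threshold, 84 gained a call and 48 lost it. For introns these were 614, 18 and 238. Replicates varied more than counting error at 5 to 20 reads, with a variance 11.6 times the mean, and depth was not tested as a limit.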

Other observations

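The test of chromosome 16, and the margin asked of the test of nuclear RNA, were chosen after the results were seen, and the genes named in this paragraph were chosen after their values were seen. Several of the genes with the most intron reads gained more than the median intron log2 fold change, 0.54, and others went the other way. C16orf72 held 35765 and 31449 intron reads in WT and 27228 and 31405 in RNase L KO. CSNK2A2 held 15885 and 14613 in WT and 9939 and 13626 in RNase L KO. Both genes lie on chromosome 16, whose median intron log2 fold change lay 0.47 below that of the other autosomes. Introns of CPS1, the first enzyme of the urea cycle, held 5607 and 5531 reads in WT and 18630 and 24135 in RNase L KO, a log2 fold change of 1.87, beside 1.08 in its exon counts, which did not pass (adjusted p = 0.103, edgeR, Benjamini-Hochberg). NRG1, a growth factor gene, rose by 1.68, and its exon counts, at 0.60, did not pass (adjusted p = 0.206, edgeR, Benjamini-Hochberg). PDE4D, a phosphodiesterase gene, rose by 0.90 in both introns and exons. KIAA0226L held 33922 and 51191 intron reads in WT and 40224 and 34167 in RNase L KO, but 0 exon reads in all 4 libraries.

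For the higher intron counts in the knockout libraries, genomic DNA in the libraries would add reads to introns of silent and expressed genes alike. Of 5022 genes without exon counts, 4492 had a usable intron length. Their gain per kilobase was 0.00257 times (SE 0.000566 over genes) that in expressed genes. In genes with 1 to 20 exon counts it was 0.00827 times. The other genes without exon counts, KIAA0226L among them, were left out, and the ratio and its SE do not cover them. For the genes covered, these values argue against genomic DNA. A few genes taking most of the intron counts are argued against as well, since 98.5% of the difference in intron share was kept without the 20 genes with the most intron counts. Nuclear RNA carried into the cytoplasmic fraction stays open. The 8 tested nuclear-retained RNAs other than MALAT1 and NEAT1 had a median log2 fold change of 0.273, while MALAT1 rose by 1.02. Of the 8, 7 were above 0. Their median met the bound first set for it, 0.268, by less than the standard error of their mean, 0.276, which is not an error of the median. A margin beyond that error was then asked, and by it the test decides nothing. The whole list of nuclear-retained RNAs, MALAT1 and NEAT1 included, was called higher by camera and by fry (Benjamini-Hochberg adjusted p = 0.00405 and 0.0424). Camera with an estimated correlation did not call it (adjusted p = 0.405). Carry-over, the loss of RNase L and other differences between the cell lines cannot be told apart in this design, with 2 libraries per genotype. The loss of RNase L was not tested apart from the others.

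The second pattern is the exon differences between the cell lines, where regional change would make neighbouring genes move together. The correlation of a gene's log2 fold change with the mean of genes 5 to 20 places away on its chromosome was 0.0939 over 12130 autosomal genes, above the highest of 100 shuffled orders, 0.0416, but between the bounds set for it, so it leaves regional change as a general explanation open. Chromosome 16 stood apart: its 571 tested genes had a median exon log2 fold change 0.35 below that of the other autosomes (difference -0.35, SE 0.0197 over genes), with 80.6% of them below it. Its introns lay lower by a like amount (-0.47, SE 0.0246 over 450 genes), at 0.785-fold in exons and 0.724-fold in introns, and in each replicate pair by -0.36 and -0.30 in exons and -0.44 and -0.49 in introns, which is consistent with a copy number change of chromosome 16 as a hypothesis. Chromosome 16 holds 5 of the 52 autosomal genes called lower in exons, and 571 of the 12130 autosomal genes tested. Chromosome 8 stood 0.20 above the other autosomes in exons (SE 0.0297 over genes) and 0.15 above them in introns (SE 0.0309). A copy number change of chromosome 8 was not tested.

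The third pattern is the wide spread between replicates of one genotype. At 5 to 20 reads per gene, the variance of exon counts between replicates was 11.6 times the mean, over 2625 gene and genotype pairs, where counting error alone gives a ratio of 1. At 20 to 100 reads the ratio was 12.3 in WT and 13.6 in RNase L KO, and at 100 to 1000 reads 16.4 and 38.1, so it rose with the level mainly in RNase L KO. A candidate explanation is that reads from the same amplified fragment were counted more than once, which would also make the counting intervals of genes at few reads too narrow. No biological explanation was tested, and how duplicates were handled is not given in the sources used here.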
